A study of Mus musculus and Homo sapiens with 24 samples.

How the data were processed

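RNA-seq was done on 24 samples, 12 of K562 and 12 of mouse LK cells. K562 is an established human line of chronic myeloid leukaemia. LK cells are bone marrow cells of C57BL/6 mice sorted as negative for lineage markers and positive for c-Kit, a population of stem and progenitor cells. Each system had 4 groups of 3 samples. In K562 these were the parental genotype or the SRSF2 P95H change, each with a control hairpin or a hairpin against RUNX1. In mice they were wild type, Runx1 knockout, Srsf2 P95H and the double mutant, with Mx1-Cre, an inducible recombinase. Per the labels, RNA was extracted with TRIzol and poly(A) libraries were made with a TruSeq kit. A single hairpin against RUNX1 was used, and the labels name no separate P95H clones. No source used here says that replicates were separate cultures or animals beyond their numbers. P-values that compare samples thus measure only the spread between these samples, which may be technical. P-values of tests over genes, events or exons do not measure that spread. The LK P95H samples carry the replicate numbers 1, 2 and 4.

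Reads were aligned with STAR to GRCh38 or GRCm38 and expression was tested with DESeq2, per the submitters' processing notes, which give no versions. The deposited expression tables hold, for each gene, the authors' log2 fold change of a mutant group over its wild-type group and the authors' adjusted p-value. The K562 tables list 60725 genes, of which 28 carry a date in place of a symbol. They give identifiers and classes but no positions or levels, and no human annotation was used here. The LK table is a selection of 989 genes made by the authors, of which 982 were found in the GENCODE M21 annotation of GRCm38 and 7 were not. Many LK P95H fold changes lie close to 0, as shrunken estimates do, and the shrinkage setting is not given in the sources used here. A deposited sheet of 53 K562 genes, chosen by the authors from these samples, holds an expression signal per library, with a normalisation that is not given in the sources used here. The deposited splicing tables hold, for each event, an inclusion level per library from 0 to 1, the change in inclusion level (mutant mean minus control mean) and a p-value or false discovery rate. Which of these it is, and the splicing tool, are not given in the sources used here. The K562 tables kept events under 0.05 and the LK tables events under 0.01, each with an absolute change of at least 0.05, as read from the deposited values. No deposited file used here holds read counts, so the depth of each sample and the reads behind each inclusion level are unknown, and no interval or detection limit that needs depth is given. The LK P95H splicing table gives levels for 2 libraries on each side. Its control levels match those of neither other LK table, so its control side was assigned to no group, and no spread is given for it.

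The design, the gene lists and most alternatives were fixed before the data were examined, and the closing section names the alternatives added later. Because no counts were used, the calls rest on the authors' values: a gene was called changed at an adjusted p-value under 0.05 with an absolute log2 fold change of at least 1. K562 counts cover protein-coding genes, and LK counts cover all classes in the authors' selection. A member of a gene list was said to rise or fall at an adjusted p-value under 0.05 whatever its fold change, and the Benjamini-Hochberg adjustment was also made over the list alone. The 17 lists were megakaryocyte and platelet, erythroid, granulocyte and monocyte, lymphoid, mast cell with basophil and eosinophil, stem and progenitor, stromal and endothelial, interferon-stimulated, NF-kB and inflammatory, p53 target, cell cycle, DNA damage response, splicing factor, reported SRSF2 P95H splicing target, myeloid neoplasm driver, RUNX and core-binding factor, and housekeeping genes. In K562 each list was set against all other protein-coding genes with cameraPR of limma 3.58.1 in R 4.3.3, with a preset correlation of 0.01 between genes. The statistic was a signed normal score recovered from the rank and value of the adjusted p-value, and the adjustment ran over the 17 lists of a comparison. A correlation estimated from the data could not be computed without values per library. On simulated scores with 1 list shifted by 1, the procedure called that list in 99, 99 and 98 of 100 draws, with 5, 2 and 0 calls of other lists over all draws. LK lists were only counted, because the selected table holds no background of unselected genes.

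Overlaps of called genes were set beside the number expected from independent draws (in LK cells from all 21951 protein-coding genes of the annotation, since the number tested is unknown) and beside 100 simulated pairs of unchanged groups that share their controls. Each simulated pair took as many top-ranked genes as were called, from noise alone. It thus treats every call as noise and is not a null model of calls past the limits. Overlaps of spliced with changed genes, and of K562 with LK genes matched by symbol, were tested with Fisher's exact test. Directions of splicing events were tested with an exact binomial test, two-sided, with Benjamini-Hochberg adjustment over event types where types are given. This test takes events as independent, which events of the same gene or exon are not, so its p-values may be too small. Non-additive change in K562 was tested as an interaction in limma on log2(signal + 1) over the 20 genes of the sheet with values in all 12 libraries. On simulated data of that size, an interaction of 1 was recovered in 29% and an interaction of 2 in 98% of cases. The simulated genes all had the median spread, without links between libraries. Real standard errors of the interaction ran from 0.237 for CD81 to 0.822 for OSGIN1. The shares recovered are thus too high for genes of wide spread. No standard errors are in the deposited tables used here, so the double fold change was set beside the sum of the single fold changes as a count without a test. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and near-identical gene copies were found with minimap2 2.31-r1302 at an identity of at least 95% over at least 50% of the transcript.

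Genes were named by a fixed rule. RUNX1 and SRSF2 were named in each comparison whose table holds them. From each comparison came the 10 largest rises and 10 largest falls among called protein-coding genes, with no filter on level because no levels are given. Up to 4 members of each list with the smallest adjusted p-values were eligible. From each splicing table came the 10 events with the largest absolute change, 1 per gene, and each event in a reported SRSF2 P95H target, in RUNX1 or in SRSF2. Genes of the authors' signal sheet were eligible where they met another part of the rule, and other genes of that sheet were named after their values were seen. Other genes named outside the rule are marked as such. A few genes that meet the rule are not named. Alternatives tried were other limits on adjusted p-value, fold change and inclusion change, all gene classes, median-centred fold changes, genes in place of events, other correlations and statistics for the list tests, another pseudocount, a filter on signal, a replicate block and leaving out each library in turn.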

Results

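The data cover RUNX1, a transcription factor of blood stem and progenitor cells, and SRSF2, a serine/arginine-rich splicing factor whose P95H change recurs in myelodysplastic syndromes. K562 cells carried SRSF2 P95H, a hairpin against RUNX1, both or neither, and mouse LK marrow cells carried Srsf2 P95H, Runx1 knockout, both or neither, with 3 samples in each of the 8 groups. The question put to the data was what each lesion, alone or combined, did to gene expression and to splicing relative to wild type. Fold changes and adjusted p-values are the authors' DESeq2 values, and read depth per sample is unknown because the tables hold no counts.

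RUNX1 knockdown in K562 was set against the control hairpin to ask what loss of the factor does alone. In the authors' deposited table RUNX1 itself (ENSG00000159216.18) fell, with a log2 fold change of -1.04 and an adjusted p of 0.00112, while SRSF2 (ENSG00000161547.14) had -0.02 with an adjusted p of 0.968. Erythroid genes rose: in the authors' deposited table SLC4A1, the anion exchanger gene of the red cell membrane, had a log2 fold change of 4.0. The blood group gene ERMAP had 1.87 and the embryonic globin gene HBE1 1.73 in the authors' deposited table (log2 fold change). Some myeloid and lymphoid genes fell, though neither list passed its test. In the authors' deposited table the log2 fold change was -3.13 for CSF2RB, a shared chain of cytokine receptors, -2.62 for MS4A3 of granulocyte progenitors and -2.05 for the lysozyme gene LYZ. The T-cell receptor component CD3E had -3.93 in the authors' deposited table (log2 fold change). The stem-cell factor receptor gene KIT rose by 3.27 and the platelet integrin gene ITGA2B had -2.65 in the authors' deposited table (log2 fold change).

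The largest rises after knockdown ran from a log2 fold change of 6.13 for the sperm sheath gene AKAP4 to 3.59 for HPSE2, a relative of heparanase, in the authors' deposited table. Between them came the metallothionein gene MT4, the renal water channel gene AQP2, SLC4A1 and the lactoferrin gene LTF of neutrophil granules. The other 4 were the muscle gene IGFN1, the secreted protease gene HTRA3 and the keratin genes KRT36 and KRT79. The largest falls in the authors' deposited table were those of C2orf70, a gene of little known function, at -8.63, the vesicle protein gene CLVS2 at -7.78 and LYNX1, a modulator of nicotinic receptors, at -7.76 (log2 fold change). Next came the vasopressin gene AVP, the cancer/testis antigen gene CT47A11 and the growth factor gene IGF1. IGF1 had -5.80 with an adjusted p of 3.29e-36 in the authors' deposited table (log2 fold change). The other falls named by the rule had values from -5.74 to -4.34 in the authors' deposited table (log2 fold change), for the glycosyltransferase gene B3GNT3, the adhesion receptor gene ADGRG5, the synaptic adhesion gene LRFN3 and the triadin gene TRDN.

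By the limits on adjusted p and fold change, 1291 protein-coding genes changed after RUNX1 knockdown, 281 up and 1010 down, so that 21.8% of the calls were rises. Without a limit on fold change 2935 genes passed and 30.8% of them rose. Of 32 erythroid genes 12 rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.54 in the authors' deposited table. Of 27 granulocyte and monocyte genes 2 rose and 11 fell (2 and 12 adjusted over the list alone). Of 19 lymphoid genes 0 rose and 5 fell (0 and 7 adjusted over the list alone). Set against all other genes, the erythroid list was higher with an adjusted p of 1.59e-07, or 0.00065 at a preset correlation of 0.05. The granulocyte and monocyte list was lower without passing, with an adjusted p of 0.0526, or 0.363 at the higher correlation. The lymphoid list was lower without passing, with an adjusted p of 0.196, or 0.433 at the higher correlation. An estimated correlation could not be computed for these list tests.

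SRSF2 P95H in K562 was compared with the parental genotype under the same control hairpin to ask what the splicing factor change does alone. In the authors' deposited table RUNX1 had a log2 fold change of -0.04 with an adjusted p of 0.941 and SRSF2 -0.27 with an adjusted p of 0.332. Stem-cell and mesenchymal genes rose: in the authors' deposited table the log2 fold change was 3.90 for KIT, 3.40 for the aldehyde dehydrogenase gene ALDH1A1, 2.98 for the angiopoietin receptor gene TEK and 2.48 for the growth suppressor gene NDN. The matrix gene SPARC had 3.34 and the collagen genes COL1A1 and COL1A2 3.10 and 2.93 in the authors' deposited table (log2 fold change). Mast-cell genes rose as well, with a log2 fold change of 3.57 for the amine transporter gene SLC18A2 and 3.09 for the prostaglandin D synthase gene HPGDS in the authors' deposited table. Interferon-stimulated genes included USP18, which removes ISG15 from proteins, at a log2 fold change of 2.06 and the apoptosis factor gene XAF1 at 1.44 in the authors' deposited table. A few DNA damage genes fell, with -1.12 for the kinase gene ATM, -0.78 for the Fanconi anaemia gene FANCD2 and -0.74 for the checkpoint kinase gene CHEK1 in the authors' deposited table (log2 fold change).

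The largest rises with P95H ran from a log2 fold change of 11.98 for the LIM-domain cofactor gene LDB2 to 7.36 for CAPN6, a calpain relative, in the authors' deposited table. Between them came the skeletal myosin gene MYH1, the heart and limb transcription factor gene HAND2, the anoctamin gene ANO4, MT4 and RP11-903H12.5, known by its clone name only. The other 3 were HRASLS, which encodes a phospholipid-modifying enzyme, the E2F partner gene TFDP3 and the G-protein subunit gene GNG11. The largest fall was that of the progesterone receptor gene PGR at a log2 fold change of -11.46 in the authors' deposited table. It was followed by the zinc finger gene ZNF804A, VAT1L, a relative of a synaptic vesicle protein gene, the transmembrane gene TMEM133 and the steroid-conjugating enzyme gene UGT2B28. Further falls were those of the cancer/testis antigen genes CTAG2 and FMR1NB, the homeobox gene ALX1 and APBB1IP, an integrin-activating adaptor of leukocytes. The falls named after PGR ran from -9.20 to -5.36 in the authors' deposited table (log2 fold change). These are changes between derivations of a cell line, and differences between clones were not separated from the P95H change.

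In all, 1221 protein-coding genes changed with P95H, 996 up and 225 down, so that 81.6% of the calls were rises, against 58.6% of the 2565 genes that passed without a limit on fold change. Of 22 stem and progenitor genes 9 rose and 3 fell (9 and 3 adjusted over the list alone). Of 16 stromal and endothelial genes 7 rose and 1 fell (9 and 1 adjusted over the list alone). Of 17 mast-cell, basophil and eosinophil genes 6 rose and 0 fell (10 and 0 adjusted over the list alone). Against all other genes the adjusted p was 3.51e-05 for the stem-cell list, 2.27e-04 for the stromal list and 6.49e-04 for the mast-cell list, all upward, and 0.00449, 0.00562 and 0.0111 at the higher preset correlation. The interferon list, with 4 rises and 1 fall among 23 genes (6 and 1 adjusted over the list alone), was higher at an adjusted p of 0.00681. The DNA damage list, with 0 rises and 4 falls among 32 genes (0 and 4 adjusted over the list alone), was lower at an adjusted p of 0.0191. At the higher correlation these last 2 lists did not pass, with adjusted p values of 0.0686 and 0.160. Of 21 lymphoid genes 5 rose and 0 fell (5 and 1 adjusted over the list alone), among them the transcription factor gene IKZF3 and the recombinase gene RAG2, and the list did not pass, at an adjusted p of 0.0518.

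The double K562 cells were compared with the parental cells with control hairpin to ask what both lesions do together. In the authors' deposited table RUNX1 had a log2 fold change of -1.24 with an adjusted p of 2.12e-06, and SRSF2 -0.28 with an adjusted p of 0.417. Erythroid genes rose further in number: in the authors' deposited table SLC4A1 had a log2 fold change of 5.38, the carbonic anhydrase gene CA2 4.94, the globin chaperone gene AHSP 4.35 and the haem synthesis gene ALAS2 2.54. Platelet genes rose too, with 6.05 for the thrombospondin gene THBS1, 3.11 for the tetraspanin gene CD9, 2.80 for the integrin gene ITGB3 and 2.79 for the myosin light chain gene MYL9 in the authors' deposited table (log2 fold change). Inflammatory genes that rose had 4.21 for IL1B and 3.18 for IL1A, both encoding interleukin-1, and 2.13 for the signalling adaptor gene TRAF1 in the authors' deposited table (log2 fold change). KIT had a log2 fold change of 6.44 in the authors' deposited table, COL1A1 4.79, the pericyte receptor gene PDGFRB 4.57, the myeloid oncogene SETBP1 4.90 and LTF 7.09. Falls in the authors' deposited table were those of LYZ at -3.21, the proteinase gene PRTN3 at -2.78, CD3E at -3.75 and the T-cell transcription factor gene LEF1 at -2.24 (log2 fold change).

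The largest rises in the double cells ran from a log2 fold change of 11.40 for RP11-599B13.6, known by its clone name only, to 8.90 for the extracellular superoxide dismutase gene SOD3 in the authors' deposited table. Between them came the paraoxonase gene PON1 and, from the single comparisons, MT4, AQP2, AKAP4, LDB2, MYH1, ANO4 and HAND2. The largest falls ran from -10.62 for PGR to -6.19 for APBB1IP in the authors' deposited table (log2 fold change). Between them came ZNF804A, VAT1L, CTAG2, TMEM133, FMR1NB, CT47A11 and TRAM1L1, a relative of a protein translocation gene. IGF1 and the cell cycle inhibitor gene CDKN1A, both also on the authors' signal sheet, had -1.95 and 1.28 in the authors' deposited table (log2 fold change).

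In the double cells 2721 protein-coding genes changed, 1610 up and 1111 down, so that 59.2% of the calls were rises, against 50.7% of the 4892 genes that passed without a limit on fold change. Of 32 erythroid genes 21 rose and 0 fell (22 and 1 adjusted over the list alone), with a median log2 fold change of 1.27 in the authors' deposited table. The list was higher than all other genes at an adjusted p of 1.73e-09. The stromal list, with 8 rises and 1 fall among 17 genes (8 and 1 adjusted over the list alone), was higher at an adjusted p of 8.03e-05. The megakaryocyte list, with 9 and 2 among 24 (9 and 2 adjusted over the list alone), was higher at 0.00103. The interferon list, with 11 and 1 among 23 (12 and 1 adjusted over the list alone), was higher at 0.00353. The NF-kB list, with 10 rises and 1 fall among 24 genes (12 and 1 adjusted over the list alone), was higher at 0.0110. The stem-cell list, with 7 and 4 among 22 (8 and 4 adjusted over the list alone), was higher at 0.0135, and the mast-cell list, with 6 and 0 among 17 (7 and 1 adjusted over the list alone), at 0.0144. At the higher preset correlation the first 4 of these lists passed, with adjusted p values of 6.04e-05, 0.00319, 0.0262 and 0.0460, and the other 3 did not, each at 0.0730. Granulocyte and monocyte genes went both ways, 8 up and 8 down among 28 (8 and 9 adjusted over the list alone).

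**Figure D1:**
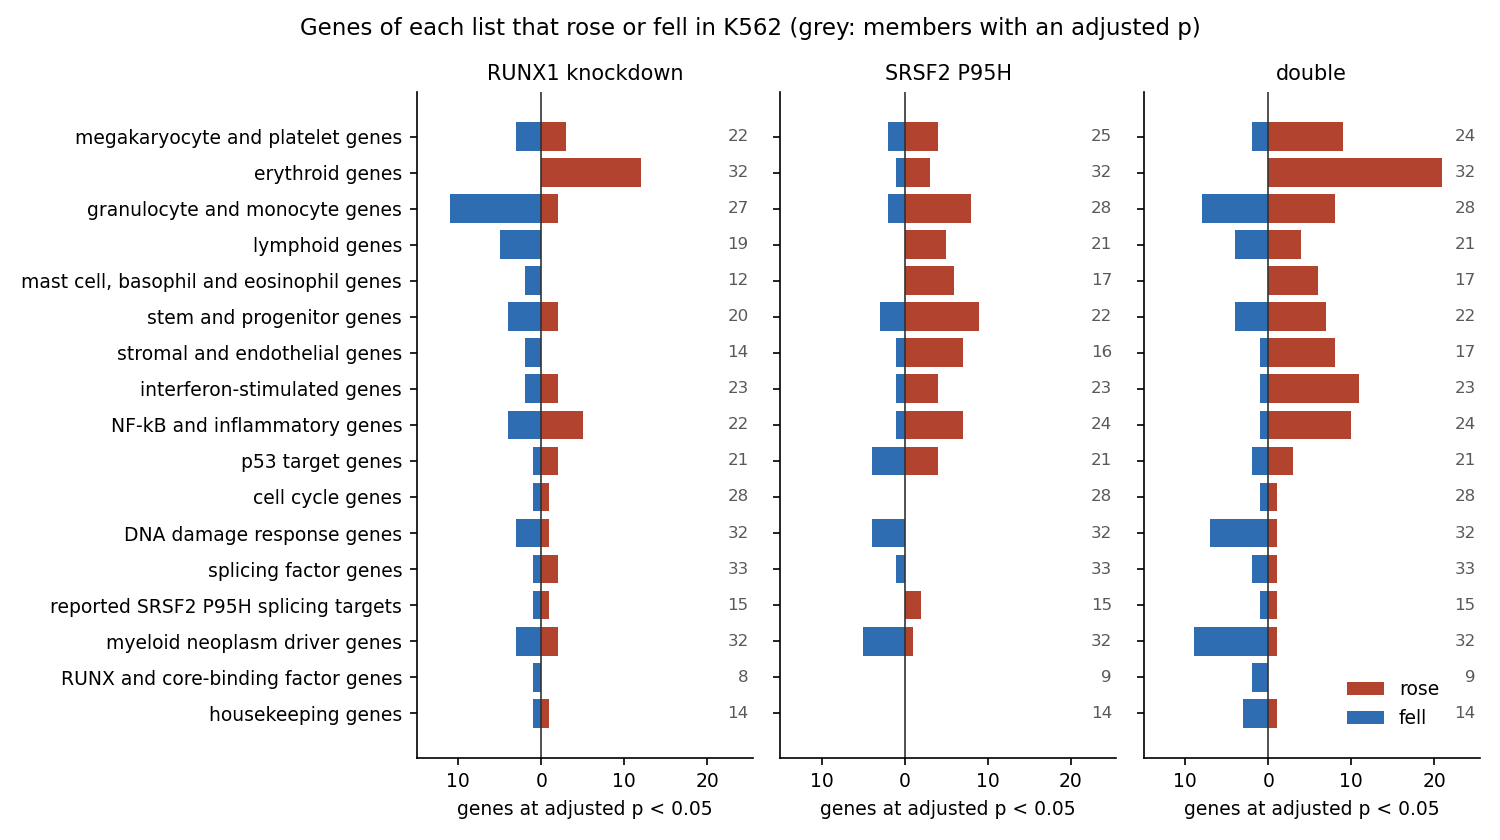
Number of genes of each list (vertical axis) that rose, to the right, or fell, to the left, at the authors' adjusted p under 0.05 in the RUNX1 knockdown, SRSF2 P95H and double K562 comparisons. Grey numbers give the members with an adjusted p. Of 32 erythroid genes 12 rose after knockdown, 3 with P95H and 21 in the double cells.

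Apart from the calls given above, no list passed the list test in K562. The splicing factor genes, 33 measured, gave 2 rises and 1 fall after knockdown, 0 and 1 with P95H and 1 and 2 in the double cells, the same numbers adjusted over the list alone. SRSF4, a relative of SRSF2, had 0.82 after knockdown and the core spliceosome gene PRPF8 had -0.64 in the authors' deposited table (log2 fold change). Among 15 reported SRSF2 P95H splicing targets, 1 rose and 1 fell after knockdown, 2 rose and 0 fell with P95H, and 1 rose and 1 fell in the double cells, again the same adjusted over the list alone. These included the granulocyte growth factor receptor gene CSF3R, which fell after knockdown and rose with P95H, and the histone methyltransferase gene EZH2, which fell in the double cells. Of 32 myeloid neoplasm driver genes 2 rose and 3 fell after knockdown (4 and 5 adjusted over the list alone). With P95H 1 rose and 5 fell (1 and 6 adjusted over the list alone), and in the double cells 1 rose and 9 fell (1 and 9 adjusted over the list alone). The transcription factor genes ETV6 and CUX1 fell after knockdown, and the kinase gene JAK2, the ubiquitin ligase gene CBL and the methyltransferase gene DNMT3A fell with P95H.

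Of 21 p53 target genes 2 rose and 1 fell after knockdown (2 and 1 adjusted over the list alone). With P95H 4 rose and 4 fell (4 and 4 adjusted over the list alone), and in the double cells 3 rose and 2 fell (3 and 2 adjusted over the list alone). The growth arrest gene BTG2 rose in each. Of 28 cell cycle genes 1 rose and 1 fell after knockdown (0 and 1 adjusted over the list alone). With P95H 0 rose and 0 fell, also adjusted over the list alone, and in the double cells 1 rose and 1 fell (0 and 1 adjusted over the list alone). The cyclin gene CCNE1 fell after knockdown and in the double cells. DNA damage genes gave 1 rise and 3 falls after knockdown and 1 and 7 in the double cells, the same adjusted over the list alone. The Fanconi anaemia gene FANCC was among the falls of both. The core-binding factor list gave 0 rises and 1 fall among 8 after knockdown and 0 and 0 among 9 with P95H, the same adjusted over the list alone. The double cells gave 0 and 2 among 9 (1 and 4 adjusted over the list alone). Of 14 housekeeping genes 1 rose and 1 fell after knockdown (1 and 2 adjusted over the list alone). P95H gave 0 and 0, also adjusted over the list alone, and the double cells 1 and 3 (1 and 4 adjusted over the list alone).

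Other lists of blood and signalling genes gave these counts. After knockdown the megakaryocyte list gave 3 rises and 3 falls among 22 genes (4 and 3 adjusted over the list alone). Mast-cell genes gave 0 and 2 among 12 and stromal genes 0 and 2 among 14, the same adjusted over the list alone. Stem-cell genes gave 2 and 4 among 20 (2 and 5 adjusted over the list alone), and interferon genes 2 and 2 among 23 (2 and 3 adjusted over the list alone). NF-kB genes gave 5 and 4 among 22 (5 and 5 adjusted over the list alone), with the chemokine genes CXCL3 and CXCL2 up and the adhesion gene ICAM1 down. P95H gave 4 rises and 2 falls among 25 megakaryocyte genes, 3 and 1 among 32 erythroid genes and 7 and 1 among 24 NF-kB genes, the same adjusted over the list alone. It gave 8 and 2 among 28 granulocyte and monocyte genes (8 and 3 adjusted over the list alone), with LTF and the calprotectin gene S100A9 up. The double cells gave 4 and 4 among 21 lymphoid genes, the same adjusted over the list alone. For some lists that did not pass, the test pointed up while the median fold change lay below 0. These were the splicing factor, SRSF2 target, driver and housekeeping lists after knockdown, the p53 and core-binding factor lists with P95H and the p53 list in the double cells.

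The authors' sheet of 53 selected K562 genes gives a signal per library, and 20 of these genes, 11 marked down and 9 marked up, have values in all 12 libraries. They were chosen on these samples, so their direction is not independent evidence, and those named here were chosen after their values were seen. IGF1 had a signal of 19.4 ± 9.96 (SD, n = 3) in wild-type cells, 0.753 ± 0.581 (SD, n = 3) after knockdown, 19.9 ± 5.61 (SD, n = 3) with P95H and 3.14 ± 2.01 (SD, n = 3) in the double cells. By these means IGF1 fell less after knockdown and more in the double cells than by its deposited log2 fold changes, so the sources differ for this gene. CORO1A, which encodes a leukocyte actin regulator, went from 40.7 ± 4.03 (SD, n = 3) to 3.11 ± 0.982 (SD, n = 3), 35.2 ± 9.47 (SD, n = 3) and 3.13 ± 1.90 (SD, n = 3) in the same order. The apoptosis inhibitor BCL2 had 1.55 ± 0.527, 0.217 ± 0.0725, 0.779 ± 0.297 and 0.167 ± 0.0184, and the cell cycle inhibitor CDKN1B 11.9 ± 1.15, 23.5 ± 2.53, 12.4 ± 1.98 and 28.0 ± 4.85 (SD, n = 3 for each). PAK1, a kinase of the cytoskeleton, had 4.98 ± 0.12, 4.31 ± 0.935, 22.2 ± 2.62 and 29.6 ± 4.97, and the metallothionein MT2A 6.57 ± 1.28, 18.4 ± 8.62, 15.0 ± 1.75 and 85.8 ± 10.9 (SD, n = 3 for each).

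**Figure D2:**
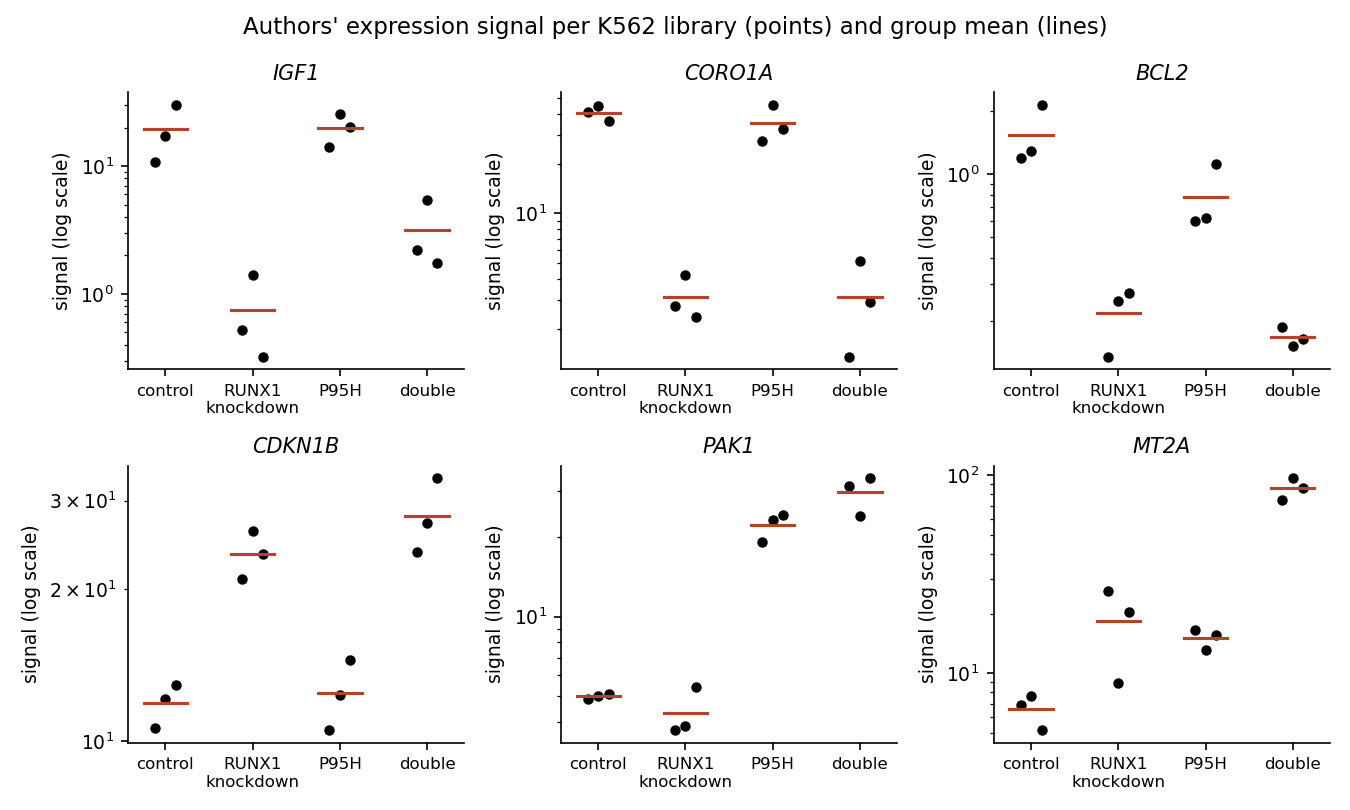
Deposited expression signal per library (points, log axis, unit not given in the sources used here) of 6 genes in the 4 K562 groups, with a line at each group mean. The mean signal of MT2A was 6.57 in wild-type, 18.4 in knockdown, 15.0 in P95H and 85.8 in double cells.

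Whether the double effect differed from the sum of the single effects was tested on these 20 genes. In limma 0 of 20 passed an adjusted p of 0.05, with a lowest adjusted p of 0.428, and 1 gene, MT2A, had an unadjusted p under 0.05. The MT2A interaction was 1.18 on the log2 scale with a standard error of 0.443 and an unadjusted p of 0.0214. The next lowest unadjusted p values were those of PAK1, with an interaction of 0.58 and a p of 0.0543, and IGF1, with 1.07 and 0.0911. The estimate was above 0 for 19 of the 20 genes and below 0 for CD80, a co-stimulatory ligand, at -0.05. For genes marked down an estimate above 0 means a smaller fall than the sum, such as -2.29 against -3.36 for IGF1. All 20 genes come from the same libraries, and the added 1 compresses changes at low signals. The count of estimates above 0 is thus not evidence of a greater than additive effect. The same sum was formed for 16266 protein-coding genes with an adjusted p in all 3 K562 comparisons. The double log2 fold change in the authors' deposited table lay at least 1 above the sum of the single ones for 571 of them and at least 1 below it for 179, without a test.

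Called genes of the single K562 comparisons were set against those of the double cells. Of 1610 genes up in the double cells 620 were also up with P95H alone, 157 with knockdown alone, 53 with both and 780 with neither. Of 1111 genes down in the double cells 467 were also down with knockdown alone, 141 with P95H alone, 46 with both and 457 with neither. P95H and double cells shared 673 rises, against 88.1 expected and a mean of 344 in simulated unchanged groups with shared controls, and 187 falls, against 14.4 and 88.5. Knockdown and double cells shared 513 falls, against 68.4 expected and 285 simulated, and 210 rises, against 22.9 and 120. Knockdown and P95H shared 53 rises, against 14.4 expected and 91.3 simulated, and 46 falls, against 13.9 and 87.0, and 106 genes were called in opposite directions. Both numbers shared by knockdown and P95H lay below the simulated ranges of 76 to 112 rises and 63 to 105 falls. The simulation treats every call as noise and leaves out any link between same-numbered libraries, so these ranges cannot decide the cause. All 3 comparisons use the same control libraries, so the excess over the expected number may come from those libraries in whole or in part.

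Runx1 knockout in LK cells was compared with wild type to ask what loss of the factor does in progenitors. Runx1 and Srsf2 are not among the genes of the authors' selection, so no expression value is given for them. Of the genes in the selected table, 5 of 7 mast-cell and 2 of 5 lymphoid genes fell. In the authors' deposited table the log2 fold change was -2.73 for the IgE receptor gene Ms4a2, -3.31 for the chymase gene Cma1, and -1.46 for the carboxypeptidase gene Cpa3. Dntt, the terminal transferase gene of lymphoid progenitors, had -1.76 and the B-cell gene Ms4a1 -2.13 in the authors' deposited table (log2 fold change). Stem-cell genes of the table that rose had 3.24 for the chromatin protein gene Hmga2, 1.37 for Tek and 1.28 for the stem-cell marker gene Slamf1 in the authors' deposited table (log2 fold change). Platelet values were 2.35 for the platelet receptor gene Treml1, 2.28 for the lipoxygenase gene Alox12 and 1.29 for the P-selectin gene Selp in the authors' deposited table (log2 fold change). The antiviral genes Oas2 and Oas3 had 1.87 and 1.35 in the authors' deposited table (log2 fold change). The knockout depends on Mx1-Cre, and the labels used here do not say when or how it was induced.

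The largest rises in the knockout ran from a log2 fold change of 9.69 for the meiotic gene Sycp1 to 4.58 for the receptor phosphatase gene Ptprm in the authors' deposited table. Between them came the enolase copy Eno1b, the chromatin protein copy Hmga1b, the predicted gene Gm9008 and the complement gene C4b. The other 4 were the meiotic gene Meiob, the olfactory receptor gene Olfr263, the cortactin-binding gene Cttnbp2 and the protease gene Prss41. The largest falls ran from -7.05 for the cytokine gene Il13 to -3.99 for the endothelial gene Esm1 in the authors' deposited table (log2 fold change). Between them came the serpin genes Serpina11 and Serpina12, the signalling gene Wnt11, the RAS-association gene Rassf10 and the amino acid transporter gene Slc36a2. The other 3 were the kinase-like gene Camkv, Klhl30, of the kelch family, and the sperm gene Adam2. Eno1b, Hmga1b, Gm9008 and C4b each have a near-identical copy in the annotation, so reads of these genes may be shared with the copy. The same limit holds for Xlr3a, Srp54a, Hbb-bt, Cd63 and Itgam, named for this or the other LK comparisons. In all 738 genes changed, 340 up and 398 down, so that 46.1% of the calls were rises.

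Counted within the selected LK table, the knockout gave 0 rises and 5 falls among 7 mast-cell genes, 0 and 2 among 5 lymphoid genes and 4 and 0 among 5 stem-cell genes. It gave 3 and 0 among 4 megakaryocyte genes, 3 and 1 among 4 stromal genes and 2 and 0 among 2 interferon genes. Of 7 NF-kB and 3 p53 target genes 0 rose and 0 fell. The erythroid and the granulocyte and monocyte list each had 1 gene in the table, the globin gene Hbb-bt and the integrin gene Itgam, which both fell. Both have a near-identical copy in the annotation. The other 7 lists have no gene in the table, and because the authors selected its genes these counts have no background to be tested against.

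Srsf2 P95H in LK cells was compared with wild type to ask what the splicing factor change does in progenitors. Among the largest falls were genes of transcription factors and of inflammatory signalling. The log2 fold change in the authors' deposited table was -3.94 for Nr4a3 and -2.40 for Nr4a1, both orphan nuclear receptor genes, and -3.14 for the zinc finger gene Egr3. The chemokine gene Cxcl2 had -3.23, Tnfaip3, an inhibitor of NF-kB signalling, -2.23 and the MAP kinase phosphatase gene Dusp5 -2.10 in the authors' deposited table (log2 fold change). Mast-cell and basophil genes of the table that fell had -2.02 for the protease gene Prss34, -1.18 for the granzyme gene Gzmb and -0.81 for Cpa3 in the authors' deposited table (log2 fold change). The remaining large falls in the authors' deposited table were those of Xlr3a, an X-linked lymphocyte-regulated gene, at -5.73, the plexin-domain gene Plxdc2 at -2.21 and the receptor gene P2ry10 at -2.09 (log2 fold change). The 5 protein-coding rises in the authors' deposited table were Xlr, of the same family as Xlr3a, at 3.73, C4b at 2.31, the lysophospholipase-like gene Lyplal1 at 1.24, the filamin-interacting gene Filip1 at 1.17 and the potassium channel gene Kcnq3 at 1.04 (log2 fold change). In all 65 genes changed, 6 up and 59 down, so that 9.23% of the calls were rises. Among 7 NF-kB genes in the table there were 0 rises and 7 falls, among them the inhibitor gene Nfkbia and the prostaglandin synthase gene Ptgs2. In the knockout and in the double cells 0 of these 7 passed. They may be in the selected table because they fell with P95H, so the share that fell is not independent evidence. Of 6 mast-cell genes 0 rose and 4 fell, and of 2 p53 targets 0 rose and 2 fell, the polo-like kinase gene Plk2 and Cdkn1a. The same limit of selection holds for these p53 targets. The megakaryocyte, lymphoid, stem-cell and stromal lists gave 0 rises and 1 fall each, among 3, 3, 5 and 2 genes, and the 2 interferon genes gave none.

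The double LK cells were compared with wild type to ask what both lesions do together in progenitors. The changes were largely of the genes named for the knockout: the 10 largest rises included Sycp1, Eno1b, Hmga1b, Gm9008, Cttnbp2, C4b, Meiob, Olfr263 and Prss41. They ran from a log2 fold change of 10.17 for Sycp1 to 5.48 for Prss41 in the authors' deposited table. The largest falls ran from -4.68 for Adam2 to -3.06 for the HMG-box gene Tox2 in the authors' deposited table (log2 fold change). Between them came Camkv, Wnt11, Il13, Rassf10, the IgM receptor gene Fcmr, the nucleosome assembly relative Tspyl5, the T-cell inhibitor gene Ctla4 and Srp54a, of the signal recognition particle. Hmga2 had 3.23, Treml1 1.83, Oas2 1.79, the tetraspanin gene Cd63 -1.39 and Dntt -1.33 in the authors' deposited table, while the T-cell receptor component Cd3d had 1.60 (log2 fold change). In all 608 genes changed, 296 up and 312 down, so that 48.7% of the calls were rises. The table gave 0 rises and 5 falls among 7 mast-cell genes, 1 and 4 among 5 lymphoid genes and 3 and 0 among 5 stem-cell genes. It gave 3 and 0 among 4 megakaryocyte genes, 2 and 1 among 4 stromal genes and 2 and 0 among 2 interferon genes. Of 7 NF-kB genes 0 rose and 0 fell, and of 3 p53 targets Eda2r, a receptor gene of the TNF receptor family, rose. Hbb-bt fell again, and the 1 granulocyte gene, Itgam, did not pass.

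Of 234 protein-coding genes up in double LK cells 169 were also up in the knockout alone, 0 with P95H alone, 1 with both and 64 with neither, and of 264 genes down, 189, 3, 0 and 72. Knockout and double cells shared 170 rises, against 2.93 expected and 35.0 simulated with shared controls, and 189 falls, against 4.02 and 43.6, with 0 genes in opposite directions. The expected numbers take all 21951 mouse protein-coding genes as background, because the number of genes tested is unknown, and are too low if fewer were tested. P95H and double cells shared 1 rise, against 0.0533 expected and 1.52 simulated, and 3 falls, against 0.613 and 10.5, with 1 gene in opposite directions. Knockout and P95H shared 1 rise, against 0.0626 expected and 1.40 simulated, and 0 falls, against 0.776 and 12.8, with 3 genes in opposite directions. The simulated values assume shared wild-type libraries, which the splicing levels leave open for the P95H comparison, so they may not apply to its overlaps. Among 788 genes with all 3 values the double log2 fold change lay at least 1 above the sum of the single ones for 150 and at least 1 below it for 83 in the authors' deposited table, without a test. Among the 491 of these called in the double cells the numbers were 43 and 40. Genes selected for a change in a single comparison can deviate from the sum through that selection.

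Genes called in K562 were matched by symbol with those called in LK cells. The background was all genes tested in K562 with a mouse protein-coding gene of the same symbol, 13510 for the RUNX1 pair. It holds genes that may not have been tested in LK cells, which lowers the expected numbers and the p-values. RUNX1 knockdown and Runx1 knockout shared 55 genes whatever the direction, against 32.2 expected, with an odds ratio of 1.87 and a two-sided Fisher's exact p of 7.74e-05. Of these, 26 fell in both, against 13.7 expected, with an odds ratio of 2.06 and a p of 0.00161. They included the lipoxygenase gene ALOX5, BCL2, the cyclin gene CCND1, CD74 of antigen presentation, the integrin gene ITGAM and the vitamin D receptor gene VDR, named after their values were seen. The LK entry behind ITGAM has a near-identical copy under the same symbol, and its DESeq2 adjusted p was 0.0486 in the authors' deposited table. Its match is therefore uncertain. The 5 genes up in both, against 3.22 expected with a p of 0.258, were ALOX12, FAIM2, an inhibitor of Fas, OLFML2B, of the extracellular matrix, PLCL1, a phospholipase relative, and the lipid phosphatase gene PLPP3, named after their values were seen. The other 24 shared genes changed in opposite directions. No expected number was formed for opposite directions in this or the other pairs. The overlaps thus do not show that directions of change were kept between K562 and LK cells. The double comparisons shared 93 genes, against 56.9 expected, with an odds ratio of 1.89 and a p of 7.93e-07. Among them 28 rose in both, with an odds ratio of 2.07 and a p of 0.00144. These included ALOX12, HMGA2 and, named after its value was seen, the apolipoprotein gene APOE. Another 17 fell in both, with an odds ratio of 1.35 and a p of 0.245, and 48 changed in opposite directions. The P95H comparisons shared 7 genes, against 3.21 expected, with an odds ratio of 2.40 and a p of 0.0390, of which PLXDC2 fell in both, 0 rose in both and 6 changed in opposite directions. Without a fold limit in K562 the P95H overlap no longer passed, with an odds ratio of 2.01 and an exact p of 0.0582.

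Splicing was compared in the same 6 pairs of groups through the deposited inclusion levels. Events named for their size are the largest of each comparison, 1 per gene. Each describes 1 listed arrangement of neighbouring exons, and the same exon can have other levels in other arrangements. The reads behind the levels are unknown and may be few, also where a level is 0 or 1. After RUNX1 knockdown in K562 a skipped exon of GHITM, a mitochondrial membrane protein gene (chromosome 10, 84150055 to 84150243, GRCh38), changed by -1. One of the endosome gene RAB5A (chromosome 3, 19975643 to 19975752) went from 1 to 0.05 ± 0.0624 (SD, n = 3). An exon of the translation factor gene EIF3E (chromosome 8, 108239958 to 108240098) went from 0.056 ± 0.049 (SD, n = 3) to 1. One of SPI1, which encodes the myeloid transcription factor PU.1 (chromosome 11, 47359853 to 47360040), went from 0.0667 ± 0.115 to 0.971 ± 0.0502 (SD, n = 3 for each). An exon of the splicing regulator gene HNRNPH1 (chromosome 5, 179618145 to 179618323) went from 0.856 ± 0.0346 to 0.164 ± 0.0540 (SD, n = 3 for each). One of CDK5RAP3, a reported P95H target that binds a kinase activator (chromosome 17, 47975514 to 47975638), went from 0.649 ± 0.0291 to 0.135 ± 0.0779 (SD, n = 3 for each). Large changes were also listed for the secretory pathway relative SEL1L3 at -0.976, the helicase gene DDX56 at -0.92, the chaperonin gene CCT8 at -0.83 and the splicing regulator gene MBNL3 at 0.829. Of 1517 events in 1025 genes 595 had higher and 922 lower inclusion, so that 39.2% were higher, with an exact binomial p of 4.38e-17. Skipped exons went down, 340 higher and 617 lower with an adjusted p of 1.30e-18, and retained introns up, 79 higher and 31 lower with an adjusted p of 1.34e-05. Groups did not overlap in 90.9% of the events, where chance gives 10%, and the tables were selected for such events.

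With SRSF2 P95H in K562 an exon of the retinoic acid receptor gene RARA (chromosome 17, 40342796 to 40342867) went from 0 to 1. For the redox enzyme gene TXNRD1 an exon (chromosome 12, 104289466 to 104289542) went from 1 to 0.11 ± 0.00721 (SD, n = 3). An exon of EPB41, which encodes a skeletal protein of the red cell membrane (chromosome 1, 28987431 to 28987905), went from 1 to 0.119 ± 0.0234 (SD, n = 3). One of the NF-kB regulator gene IKBKG (chromosome X, 154560407 to 154560559) went from 1 to 0.289 ± 0.241 (SD, n = 3). Of the reported P95H targets, the kinase gene FYN had an exon (chromosome 6, 111699515 to 111699670) that went from 0.41 ± 0.06 to 0.199 ± 0.0269 (SD, n = 3 for each), and CDK5RAP3 a retained intron that changed by 0.17. Of 631 events in 505 genes 260 had higher and 371 lower inclusion, so that 41.2% were higher, with an exact binomial p of 1.14e-05. Skipped exons made up the difference, 175 higher and 305 lower with an adjusted p of 1.58e-08, while retained introns gave 12 higher and 8 lower. Groups did not overlap in 89.2% of the events, where chance gives 10%.

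In the double K562 cells EPB41 lost a nearly identical exon (chromosome 1, 28987448 to 28987905), from 1 to 0.026 ± 0.00954 (SD, n = 3). For the repair gene ERCC1 an exon (chromosome 19, 45449173 to 45449244) went from 1 to 0.0797 ± 0.0695 (SD, n = 3), and the HNRNPH1 exon from 0.856 ± 0.0346 to 0.123 ± 0.0393 (SD, n = 3 for each). An exon of ARMC10, a reported P95H target of the mitochondrial membrane (chromosome 7, 103083066 to 103083132), went from 0.923 ± 0.134 to 0.267 ± 0.0962 (SD, n = 3 for each). The exon of HNRNPA2B1, an RNA-binding protein gene among the reported targets (chromosome 7, 26193251 to 26193373), went from 0.998 ± 0.00289 to 0.75 ± 0.0845 (SD, n = 3 for each). A cassette exon of SRSF2 itself (chromosome 17, 76735772 to 76735875) rose from 0.102 ± 0.0162 to 0.219 ± 0.0521 (SD, n = 3 for each). A mutually exclusive exon of RUNX1 (chromosome 21, 34834410 to 34834601) went from 0.970 ± 0.0156 to 0.866 ± 0.0193 (SD, n = 3 for each). The largest listed changes also included the nuclease gene DNA2 at -1, the differentiation gene NDRG4 at -0.98 and the respiratory chain gene SDHA at -0.968, while INTS3, a reported target of the integrator complex, changed by -0.137. Of 3300 events in 1966 genes 1007 had higher and 2293 lower inclusion, so that 30.5% were higher, with an exact binomial p of 9.33e-114. Skipped exons gave 540 higher and 1732 lower with an adjusted p of 4.14e-144, and retained introns 65 and 60 with an adjusted p of 0.721. Groups did not overlap in 93.2% of the events, where chance gives 10%.

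**Figure D3:**
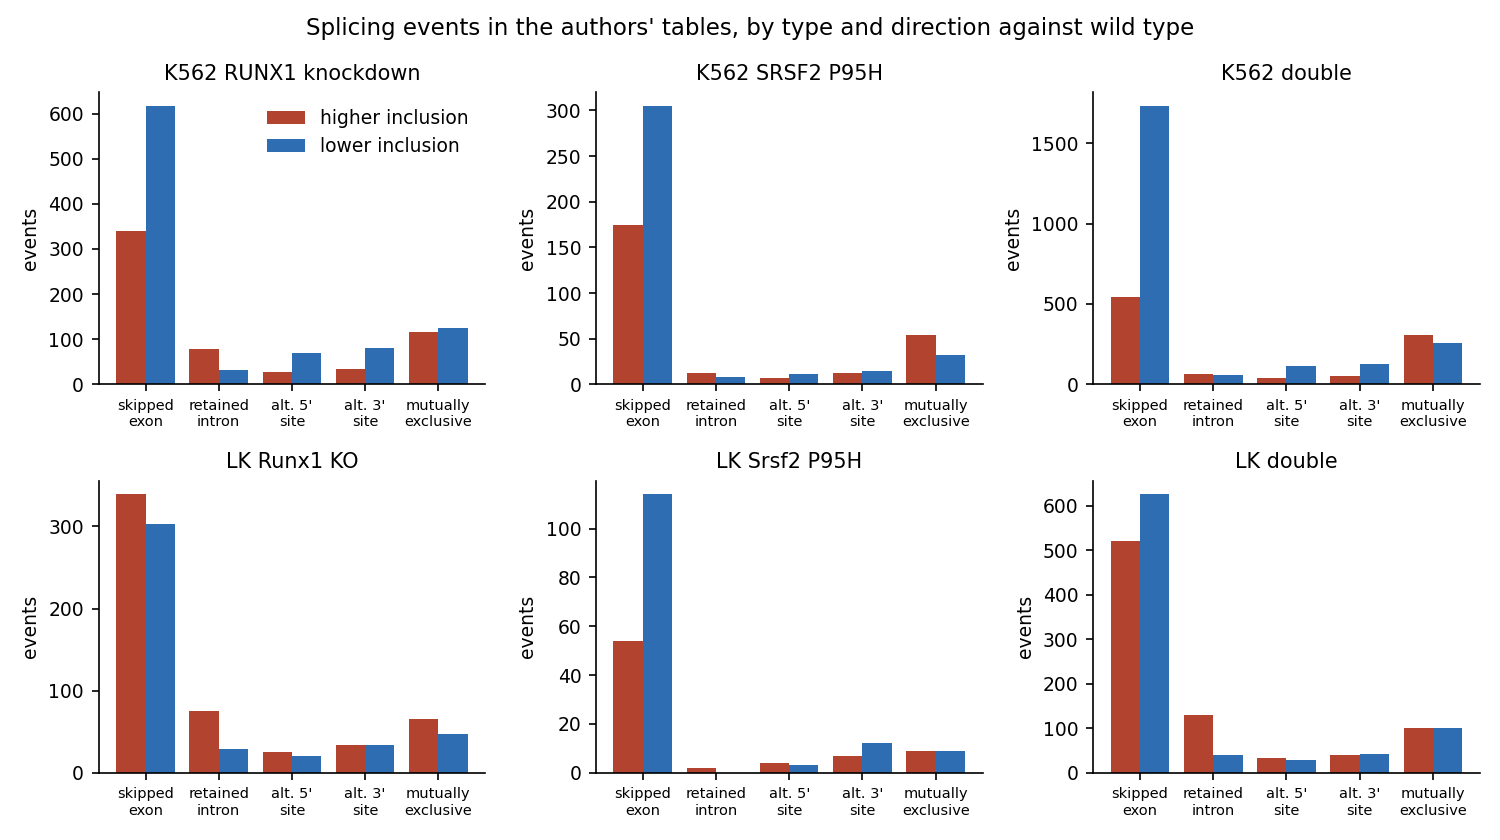
Number of deposited splicing events of each type with higher inclusion (left bar of each pair) or lower inclusion (right bar) in the mutant group, for the 6 comparisons. Among skipped exons 540 were higher and 1732 lower in double K562 cells, and 520 were higher and 625 lower in double LK cells.

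In Runx1 knockout LK cells the largest change was in Runx1 itself. These cells carry a Runx1 knockout, so loss of an exon from the gene cannot be told apart here from a change in splicing. A coding exon of 105 bases (chromosome 16, 92668708 to 92668812, GRCm38) was listed in 5 skipped-exon events that differ in the neighbouring exons. In the event with the largest change its level was 0.999 ± 0.00115 (SD, n = 3) in wild-type and 0.0353 ± 0.0293 (SD, n = 3) in knockout libraries. Over the 5 events the knockout mean ran from 0.0353 to 0.479 and single knockout libraries from 0 to 0.721, while the wild-type libraries lay at 0.922 or above. The exon of the mitochondrial calcium channel regulator Micu3 (chromosome 8, 40359410 to 40359448) went from 1 to 0.160 ± 0.0503 (SD, n = 3). One of Ssbp4, a DNA-binding protein gene (chromosome 8, 70600009 to 70600062), went from 0.0793 ± 0.0137 (SD, n = 3) to 1. An alternative splice site of Hcfc1r1, a regulator of a transcription cofactor (chromosome 17, 23674535 to 23674675), went from 0.978 ± 0.00872 to 0.0537 ± 0.0327 (SD, n = 3 for each). An exon of the splicing kinase gene Clk1 (chromosome 1, 58420121 to 58420211) went from 0.50 ± 0.0879 to 0.706 ± 0.0236 (SD, n = 3 for each). An exon of Csf3r (chromosome 4, 126034170 to 126034339) went from 1 to 0.607 ± 0.154, and the macrophage gene Lacc1 had an exon that changed by -0.885. Of 971 events in 697 genes 538 had higher and 433 lower inclusion, so that 55.4% were higher, with an exact binomial p of 8.36e-04. This call was lost at a change of at least 0.1, where 52.8% were higher with an exact p of 0.183, and also at 0.2, at a p under 0.001 and without the control library listed first. Retained introns gave 75 higher and 29 lower with an adjusted p of 3.68e-05, and skipped exons 339 and 303 with an adjusted p of 0.279. Groups did not overlap in 72.4% of the events, where chance gives 10%.

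**Figure D4:**
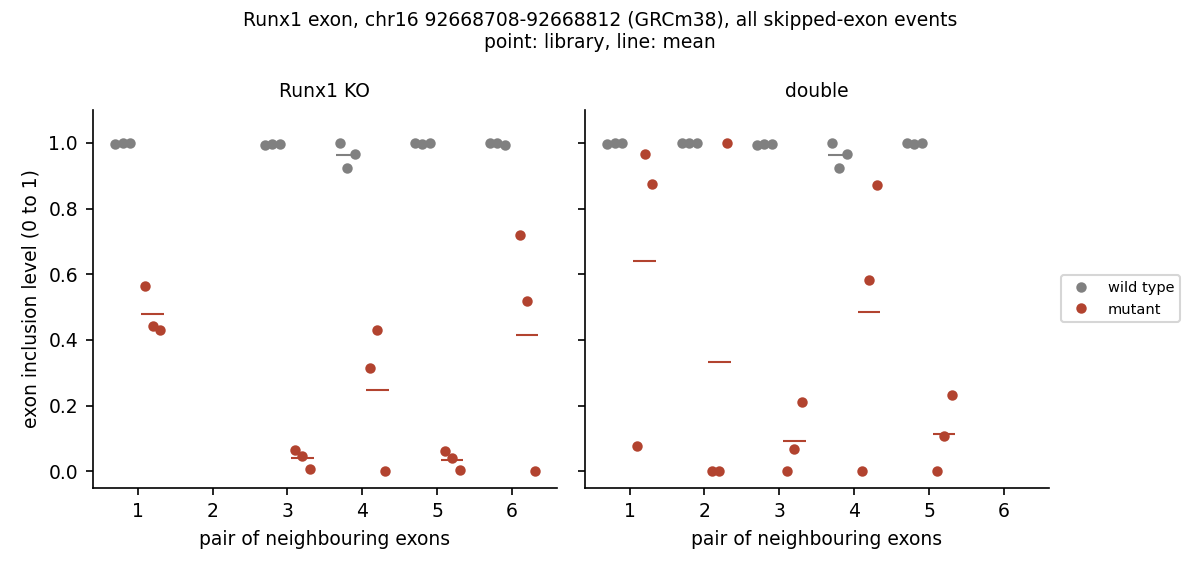
Inclusion level (0 to 1) of the Runx1 exon on chromosome 16, 92668708 to 92668812, in each library (points, with a line at the mean) of wild-type and mutant LK groups, for each pair of neighbouring exons with a listed event. Wild-type libraries lie at 0.922 or above, knockout libraries between 0 and 0.721 and double libraries between 0 and 1.

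With Srsf2 P95H in LK cells the deposited levels cover 2 mutant libraries, and the control levels cannot be tied to the wild-type group, so changes are given without a control spread. An exon of Ezh2 (chromosome 6, 47541845 to 47541970), coding and 126 bases long, had 0.670 ± 0.0163 (SD, n = 2) against 0.802. An exon of Hnrnpa2b1 (chromosome 6, 51464428 to 51464547) had 0.440 ± 0.0120 (SD, n = 2) against 0.684. An exon of the G-protein gene Gnas (chromosome 2, 174336747 to 174336791) had 0.757 ± 0.0219 (SD, n = 2) against 0.627. An alternative splice site of the lymphoid transcription factor gene Irf4 (chromosome 13, 30753445 to 30753589) had 1 against 0.0985. Changes from one extreme of inclusion to the other were listed for Ankhd1, of the Hippo pathway, Baz2a, a chromatin remodeller of ribosomal genes, Bora, a mitotic kinase cofactor, and Sympk, a scaffold of RNA 3' end processing, and Bin1, a membrane-bending protein gene, had -0.9. Of 214 events in 177 genes 76 had higher and 138 lower inclusion, so that 35.5% were higher, with an exact binomial p of 2.70e-05. Skipped exons gave 54 higher and 114 lower with an adjusted p of 2.13e-05.

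In double LK cells the Runx1 exon was again listed in 5 skipped-exon events. Its lowest mean was 0.0937 ± 0.107 (SD, n = 3) and its highest 0.639 ± 0.489 (SD, n = 3), where the libraries lay at 0.077, 0.966 and 0.875. In another event 1 double library had a level of 1. In the event of lowest mean the libraries lay at 0.001, 0.069 and 0.211, and in the next at 0.002, 0.108 and 0.233. The library listed first was lowest or tied lowest in each of the 5 events. These events share the exon, and the reads behind their levels are unknown and may be few. A difference in loss of the exon between libraries is thus possible but not shown. An exon of the zinc finger gene Zfp106 (chromosome 2, 120513617 to 120513688) went from 0.0477 ± 0.0826 to 1 and that of Micu3 from 1 to 0.0927 ± 0.0289 (SD, n = 3 for each). Of the reported P95H targets, the Hnrnpa2b1 exon went from 0.647 ± 0.0565 to 0.398 ± 0.0359 and that of Gnas from 0.572 ± 0.0330 to 0.706 ± 0.0512 (SD, n = 3 for each). An exon of Fyn (chromosome 10, 39529919 to 39530074) went from 0.918 ± 0.0761 to 0.681 ± 0.0292 (SD, n = 3 for each). A splice site of the transcriptional repressor gene Bcor (chromosome X, 12048303 to 12048647) went from 0.548 ± 0.0659 to 0.417 ± 0.0105, and the Csf3r exon from 1 to 0.726 ± 0.278 (SD, n = 3 for each). Of 1660 events in 1157 genes 823 had higher and 837 lower inclusion, so that 49.6% were higher, with an exact binomial p of 0.75. Retained introns gave 129 higher and 40 lower with an adjusted p of 2.02e-11, and skipped exons 520 and 625 with an adjusted p of 0.00526. Groups did not overlap in 75.2% of the events, where chance gives 10%.

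The same events recurred between comparisons. In K562 knockdown and double cells shared 632 events, 632 of them in the same direction, and P95H and double cells 273 with 273. Knockdown and P95H shared 31 with 28, the exceptions being in ELMOD3, a regulator of small GTPases, the centrosome gene NDE1 and the kinase gene PRKCZ, named after their values were seen. In LK cells knockout and double shared 366 events, 365 in the same direction, the exception being in the receptor phosphatase gene Ptpro, also named after its value was seen. P95H and double LK cells shared 54 events with 52 in the same direction, and knockout and P95H 4 with 3. Control levels were identical in the shared events of the K562 pairs and of LK knockout with double cells, so those counts are not independent evidence of a shared effect. Identical control levels numbered 0 in pairs with the LK P95H table. Whole sets of levels were compared, and a set of 2 libraries cannot equal a full set of 3, so this 0 decides nothing. Whether its control libraries are shared is open. Spliced genes of K562 and LK cells matched by symbol numbered 68 for RUNX1, 11 for P95H and 223 for the double comparison. The 11 included the nuclear export receptor gene XPO1, the growth-arrest transcript gene GAS5 and the mitotic gene PMF1, named after their values were seen.

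Spliced genes were set against changed genes in K562. After knockdown 65 genes were both, against 76.6 expected, with an odds ratio of 0.830 and a two-sided Fisher's exact p of 0.176. With P95H 40 were both, against 30.5 expected, with an odds ratio of 1.35 and a p of 0.0861, and in the double cells 213, against 282 expected, with an odds ratio of 0.699 and a p of 1.36e-06. Without a limit on fold change the odds ratio was 1.40 for knockdown, 1.57 for P95H and 1.07 for the double cells, so its direction depended on that limit for knockdown and the double cells. In LK cells 32 genes were both spliced and changed in the knockout, 1, Irf4, with P95H and 23 in the double cells, without a test because of the selection of the table.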

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

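Alternatives chosen only after the data were seen were leaving out single libraries, the 0.1 pseudocount, the replicate block, a fold limit of 2 for overlaps and for the deviation from the sum of single effects, and the counts of groups that do not overlap. Over all results 278 alternative values were computed, of which 206 kept their direction and their side of the threshold or stayed within 1.5 times the count, 40 moved further, 14 no longer passed, 9 newly passed and 9 reversed. The 206 include values that could hardly change, such as K562 splicing counts without 1 library and interaction counts that stayed at 0. Their number is therefore no measure of stability. Causes were not tested except where a setting counts fewer or more genes by its construction.

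Counts of changed genes followed the limit on fold change. At an absolute log2 fold change of at least 2 they were 302 for RUNX1 knockdown, 514 for P95H and 1007 for double cells in K562, and 233 for Runx1 knockout, 12 for P95H and 170 for double LK cells. Without a fold limit they were 2935, 2565 and 4892 in K562. With all gene classes P95H gave 1954 and the double cells 4495. An adjusted p under 0.01 and median-centred fold changes left each count within 1.5 times its value.

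Counts of splicing events fell with stricter limits. At an absolute change of at least 0.2 there were 828 after K562 knockdown, 1947 in double K562 cells, 344 in Runx1 knockout, 104 in LK P95H and 408 in double LK cells, and at 0.1 there were 614 in Runx1 knockout and 962 in double LK cells. At a p under 0.001 there were 686, 192 and 1661 in the 3 K562 comparisons and 516, 83 and 922 in the 3 LK comparisons. Counting genes in place of events gave 1966 for double K562 cells. The K562 and LK P95H shares of events with higher inclusion stayed below 50% and past the threshold at the stricter limits and with genes counted. Leaving out a library only filtered again the events that the authors had selected with all libraries, without a new p-value per event, and removed at most 3 events in K562, so it says nothing about stability there.

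The share of events with higher inclusion in Runx1 knockout LK cells was the least stable in its test. It was 55.4% as reported, and without passing the test 52.8% at a change of at least 0.1, 50% at 0.2 and 51.6% at a p under 0.001. Leaving out 1 library at a time gave 53% to 56.0%, and without the control library listed first the share of 53% had a p of 0.0794. In double LK cells the share of 49.6% became 44.4% at a change of at least 0.2, which passed with a p of 0.0258, and 50.7% when genes were counted. Leaving out 1 library at a time gave 47.6% to 50.6% there, with 50.6% without the mutant library listed first, 50.2% without the mutant library listed last and 47.6% without the control library listed first.

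Gene lists past the threshold numbered 3 after knockdown with the log2 fold change as the statistic, where the granulocyte and monocyte list passed at 0.000826 and the lymphoid list at 0.00352 and the erythroid list kept its call. For P95H there were 3 at a preset correlation of 0.05, 3 with the log2 fold change and 10 with ranks, 5 up and 5 down. For the double cells 4 passed at the preset correlation of 0.05. The stem-cell, stromal and mast-cell lists with P95H passed under each of these settings, with adjusted p values from 2.91e-06 to 0.0111. In the double cells the stem-cell list did not pass with ranks, at 0.374, nor the interferon list with the log2 fold change, at 0.0622.

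Overlaps of changed genes in the same direction numbered 311 for knockdown with P95H, 1795 for knockdown with double cells and 1678 for P95H with double cells without a fold limit. At a fold limit of 2 they were 26, 128 and 375 in K562, 91 for knockout with double LK cells and 1 for P95H with double LK cells. The overlap of spliced with changed genes changed direction without a fold limit, to an odds ratio of 1.40 after knockdown with an exact p of 4.01e-05 and to 1.07 in double cells with an exact p of 0.247, and P95H then passed at 1.57 with an exact p of 2.71e-04. Between K562 and LK cells without a fold limit in K562, the odds ratio was 0.921 for genes up after loss of RUNX1, 3.56 for genes up and 0.732 for genes down with P95H, and 0.832 for genes down in double cells, each on the other side of 1. None of these passed Fisher's exact test with or without the limit. For genes up with P95H the number shared went from 0 to 1, with 4 LK calls. For P95H genes in any direction it was 2.01 and no longer passed, with an exact p of 0.0582.

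The interaction test in K562 gave 0 genes under each alternative run, including a filter on signal that left 13 genes, the 0.1 pseudocount, the replicate block and leaving out each of the 12 libraries. Same-numbered libraries of different groups shared deviations over 0.1 in correlation in 15 of 18 pairs, from -0.102 to 0.792 across genes. On average, 12 of 12 samples correlated best with the libraries of their own number in the other groups. The numbers may thus mark batches, though nothing in the labels says that libraries were paired. The main interaction test left this link out, and the replicate block included it. With a deviation from the sum of at least 2, the count was 127 genes in K562 and 46 in LK cells, against 750 and 233 at 1. Filters on mean level, a new adjustment over all p-values, other size factors, tools and count filters, leaving out replicates in the expression tables, an estimated correlation, the variance allowance for shared controls and the test of additivity over all genes were not run, because the tables used hold no counts, levels, unadjusted p-values or standard errors. The no-fold, centred and list-test alternatives were not run for the selected LK table. The unknown depth limits what can be said of the fold changes of genes with few reads.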

Other observations

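The tests of the metallothionein genes, of the Runx1 locus, of the genes that fell in LK P95H cells and of other splits of the libraries were chosen after the result was seen. The motif tests and the test of gene copies were fixed earlier.

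Metallothionein genes, which bind zinc and copper, stood out among the rises and were chosen for their values. At the authors' adjusted p under 0.05, 2 of 7 rose after RUNX1 knockdown, 5 of 8 with P95H and 7 of 8 in the double K562 cells, with median log2 fold changes of 0.33, 1.18 and 3.62 in the authors' deposited table. In that order MT4 had 5.43, 7.83 and 10.82, MT2A 1.42, 1.05 and 3.58, and MT1E 0.15, 2.41 and 4.74 in the authors' deposited table. MT1A, at 1.07 with an adjusted p of 0.0773 in the authors' deposited table, was the member that did not pass in the double cells. The MT2A interaction did not pass its adjustment, so a greater than additive rise was not shown.

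Exons with changed inclusion in LK P95H cells differed in sequence by direction. SRSF2 binds CCNG and GGNG motifs, and P95H is known to favour CCNG, so the share of CCNG among both motifs was compared between exons of higher and lower inclusion with a two-sided permutation test. The difference was 0.274 with P95H, from 0.633 in 52 exons of higher and 0.360 in 98 of lower inclusion, with a 95% interval of 0.181 to 0.369 and a p of 4e-05, and 0.261 in double cells, over 473 and 537 exons, with an interval of 0.228 to 0.296 and a p of 2e-05, the smallest the permutations can give. In Runx1 knockout without P95H it was -0.0245 over 304 and 257 exons, with an interval of -0.0726 to 0.0254 and a p of 0.337, which argues against a split that arises without P95H. A shift of exon choice by the mutant protein is a candidate explanation for both P95H results, while the unmatched control of the P95H table stays a limit.

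The genes that fell in LK P95H cells mostly did not fall in double cells that also carry P95H. Of the 59 genes a share of 0.119 fell there, namely the adhesion gene Cdh1, Gzmb, Irf4, the Notch ligand gene Jag2, the receptor gene Lilr4b, which has a near-identical copy, Prss34 and the transporter gene Slc35d3, and a share of 0.0339 fell in Runx1 knockout, Cdh1 and Gzmb. Their median log2 fold change was -1.39 with P95H, -0.14 in the knockout and -0.16 in the double cells in the authors' deposited table. High levels in the wild-type libraries of the P95H comparison, for example from handling, could explain the falls. This needs controls other than those of the other comparisons, which is open. An effect of P95H that loss of Runx1 removes could also explain them. The genes were selected for their fall with P95H, so smaller falls elsewhere may come in part from that selection. These and other explanations cannot be told apart, because no table used here gives levels per LK library.

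Large changes in Runx1 knockout LK cells included copies of abundant genes, such as Hmga1b at 7.81 beside Hmga1 at -1.51 in the authors' deposited table (log2 fold change). Reads shared between near-identical copies as the whole cause were argued against, since 10.4% of 192 calls of at least 2 have such a copy. The share was 10.7% of 21866 protein-coding genes, a ratio of 0.977 with a Fisher's exact p of 1. That background holds genes that may not have been tested in LK cells, so the ratio cannot tell whether such genes are enriched among the calls. Variants carried with the Runx1 locus were argued against as the main cause, since 6 of 732 calls lay within 10 Mb of it, a ratio of 1.49 to all genes with an exact binomial p of 0.309. For single genes such as Hmga1b and Eno1b in the knockout, shared reads or a strain variant may still account for the value. Loss of Runx1 stays a hypothesis for the set, and strain differences outside that region were not tested.

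For the interaction test in K562 the real count was 0, which each split of the 12 libraries reaches by definition (100 of 100 random splits, with a highest count of 8 among the others), so this comparison decides nothing.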
